A study of Mus musculus with 4 samples.

How the data were processed

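The material was kidney tissue of wild-type mice, digested and sorted for CD45-positive cells and CD3-positive T cells, with 1 library each for day 0 (healthy), day 3, day 7 and day 14 of the disease, sequenced for gene expression and for T cell receptors on a droplet platform. Per the submitters' processing notes, the authors used Cell Ranger, Seurat and the mouse build mm10, with versions not given in the sources used here. The deposited expression values were expected counts per gene and cell, and nearly all of them (33727691 of 33799803 values above 0) were not whole numbers, most lying just under one. Of the values above 0, 85.1%, 85.0%, 75.4% and 88.5% lay within 0.1 below a whole number on days 0, 3, 7 and 14. The sums were 2.70%, 2.20%, 3.82% and 1.91% below those of the values raised to the next whole number. Which tool the authors used to make the estimated counts non-whole was not stated. Whether background RNA had been subtracted was not stated either, so counts of 0 and levels read as background may follow such a step. The receptor tables, deposited by the authors in the Cell Ranger contig format, gave a count of reads and of UMIs for each assembled chain. The day of each cell came from another deposited table of cell barcodes, as text. The receptor barcodes found among the cells of their own day numbered 2009 of 2796, 751 of 1080, 1433 of 1883 and 1582 of 2435 on days 0, 3, 7 and 14.

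All 22744 deposited cells were kept. Counts were normalised to 10000 per cell and log-transformed, and 2000 variable genes without receptor and immunoglobulin variable genes, 30 components, 15 neighbours and Leiden clustering at resolution 1 gave 34 clusters, without batch correction. The T cells were clustered again alone, into 18 clusters, and 1 of these with NK markers and few CD3 genes was counted with the NK-like cells. Clusters were named from 37 marker lists fixed before the data were examined, by the mean standardised level of each list. 5 clusters of all cells and 11 of the T clusters stayed unnamed, because non-immune markers led, no list scored high enough or several did. T clusters could only be named naive, CD8 effector or memory, Th17, Treg or gamma-delta T. Lists of other T cell kinds, such as Th1 and NKT, could not name a T cluster, even where they led. The score limits for leaving a cluster unnamed were set after the data had been seen. Scrublet called 1, 3, 0 and 0 doublets on the 4 days, under 0.5% of the cells of each library. Its calls were not relied on, and no cell was removed by it. Whether doublets had been removed before deposit was not stated.

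Gene expression was compared from summed counts per class and library, with the sums rounded to whole numbers first. Levels are CPM of the class total, and each of days 3, 7 and 14 was set against day 0. Shares carry exact Clopper-Pearson intervals, sums exact Poisson intervals, ratios exact conditional binomial intervals and differences of shares Newcombe intervals, all at 95%. With 1 library per day no test or standard error was computed, and changed genes were not counted over all genes. A ratio against a count of 0 is given as a lower bound against a floor of 3 counts. For 20 gene lists fixed before the data were examined, the median log2 ratio of the members with at least 20 counts was taken, with 0.5 counts added, and members of a list were counted as higher or lower at 2-fold with an interval excluding 1. The percentile of each median among 10000 random lists matched on expression was also computed. The named genes of T cells and phagocytes were, for each day, the 5 highest and 5 lowest by the interval bound nearest to 1, among genes with at least 50 counts and a count in at least 5% of the cells of 1 library, and for the other classes the 3 highest and lowest. Mitochondrial, ribosomal, haemoglobin, immunoglobulin, receptor, sex-linked, predicted and proximal tubule marker genes were left out of that ranking. From each list the 4 members with the most counts and those at least 4-fold apart by the interval bound could also be named.

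Shares of T cells with a count of a gene were taken after thinning each cell to 1053 counts, the 10th percentile of T cell depth, with a value of at least 0.5 read as 1 count. A clonotype was the set of productive, high-confidence chains of a cell by V gene, J gene and CDR3 amino acids, in cells with exactly 1 beta and 1 or 2 alpha chains, and the repertoires were thinned to 770 cells in 1000 draws. Gene positions came from GENCODE M21 on GRCm38, where 217 of 218 symbols looked up were matched. The methods were tested on simulated T cell counts. Of 100 genes made 2-fold different, 99, 99 and 100 were found at the depths of days 3, 7 and 14, and of 100 made 4-fold different 99, 100 and 100. The ratio intervals held the true ratio for 96.0%, 95.6% and 95.6% of the genes, and 5.31%, 5.82% and 8.75% of the unchanged genes had an interval that left out 1. The totals were rescaled after genes were changed, so the true ratio of the unchanged genes was not exactly 1. The counts were drawn from the Poisson model that the intervals assume. The simulation therefore checks the computation and not whether that model describes the deposited values. The share intervals held the true share in 96.2% of simulations. Of the alternatives, 24 were fixed before the data were examined and 13 were added after. The planned weighting of T subsets was done over the 7 T clusters with at least 20 cells in every library, and not over named subsets. The Th17-like and the Treg-like clusters fell short of that number, and 2 of the added alternatives were run to separate leaving clusters out from weighing them. The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.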

Results

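Single-cell RNA and T cell receptor sequences were compared between 4 libraries of immune cells from kidneys of wild-type mice. The day 0 library came from untouched, healthy kidneys, and the other libraries from days 3, 7 and 14 of crescentic glomerulonephritis (cGN), a disease in which inflammatory cells fill the glomeruli. Cells positive for CD45, a protein of all leukocytes, and T cells positive for CD3 had both been sorted. There was 1 library per day, so there were no replicates and no test of a difference between days could be made. The expression table held 22744 cells and 32252 genes. Days 0, 3, 7 and 14 had 7407, 5118, 5847 and 4372 cells, with summed expected counts of 24814444, 25512466, 19075749 and 19904401. The median count per cell was 2836, 3684, 2469 and 3601 in the same order, and the median mitochondrial share was 1.14%, 1.23%, 1.85% and 1.16%. The title of the libraries labelled day 7 and day 14 in the other label fields named the opposite day. The other fields were followed. The receptor table and the cell table carried the same day label, as 1433 of the 1883 barcodes in the day 7 receptor table were cells marked day 7 and 13 were cells marked day 14. This does not show whether that label or the title gives the true day, so every value of days 7 and 14 rests on the other fields. Values in brackets after a share, a ratio or a difference are 95% intervals, which cover counting error only and not the differences between animals or between preparations.

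The first comparison asked how the make-up of the renal immune cells differed over the course of the disease. Neutrophil-like cells, the first blood leukocytes to enter inflamed tissue, made up 2.39% (1.98 to 2.86) of the cells outside the T class at day 0 and 16.2% (14.8 to 17.6) at day 7, a difference of 13.8 percentage points (12.4 to 15.3). B-like cells, which make antibodies, had a lower share on every disease day, with 32.3% (31.0 to 33.7) at day 0, 12.7% at day 3, 7.13% (6.19 to 8.16) at day 7 and 6.99% at day 14. Mononuclear phagocyte-like cells, that is monocytes and macrophages, stood at 33.9% (32.6 to 35.2) at day 0 and at 52.5% (51.0 to 54.1) at day 3. Dendritic-like cells, which present antigen to T cells, stood at 7.37% (6.65 to 8.14) at day 0 and at 20.8% (19.2 to 22.6) at day 14.

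Among the cells outside the T class, the difference from day 0 was -25.2 percentage points (-26.8 to -23.5) for B-like cells at day 7, 18.6 percentage points (16.6 to 20.7) for phagocytes at day 3 and 13.5 percentage points (11.6 to 15.4) for dendritic-like cells at day 14. Neutrophil-like cells held 8.41% at day 3 and 8.79% at day 14, and dendritic-like cells held 7.14% at day 3 and 15.3% at day 7. Phagocytes held 26.7% at day 7 and 41.8% at day 14. NK-like cells held 10.1% at day 0, 12.8% at day 3, 13.4% at day 7 and 10.01% at day 14. The T cluster with NK markers was counted with them. It gave 237 of 488, 68 of 524, 12 of 365 and 76 of 222 of these cells on the 4 days. Cluster 12, also NK-like, held 209, 345, 40 and 117 cells, and cluster 18 held 42, 111, 313 and 29. The nearly level share therefore rested on the reassigned T cluster, and the other NK-like cells were not level. Cells like type 2 innate lymphoid cells (ILC2), which release type 2 cytokines, held 3.30% (2.82 to 3.84) at day 0, 1.10% at day 3, 1.36% at day 7 and 1.76% at day 14. Plasmacytoid dendritic-like cells held 0.929%, 0.731%, 2.02% and 0.676% on the 4 days, and basophil-like or mast-like cells 0.248%, 1.07% (0.780 to 1.44), 0.294% and 0.271%. T-like cells were 34.6%, 19.8%, 53.4% and 49.3% of all cells, shares that the mixing of the CD45 and CD3 sorts can set, which is why the other shares leave T cells out.

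Within the phagocytes of day 3 the share of macrophage-like cells was lower, and the shares of both kinds of monocyte-like cells were higher, than in the healthy library. Macrophage-like cells were 73.6% (71.4 to 75.7) of the phagocytes at day 0, 33.4% (31.4 to 35.4) at day 3, 55.6% at day 7 and 60.6% at day 14. Classical monocyte-like cells, which enter tissue from blood, were 6.58% (5.43 to 7.89) at day 0, 26.5% (24.6 to 28.4) at day 3, 14.03% at day 7 and 11.96% at day 14. Nonclassical, or patrolling, monocyte-like cells held 18.3%, 31.1%, 19.9% and 18.4% of the phagocytes. Cells like damage-associated macrophages were 1.52% (0.988 to 2.24) at day 0 and 9.05%, 10.5% (8.33 to 12.9) and 9.05% on days 3, 7 and 14. With the clusters drawn from more variable genes and components, the differences of these cells from day 0 were 0.312 percentage points at day 7, from 8.93, and 0.704 at day 14, from 7.53. The classical monocyte-like difference from day 0 was 29.6 percentage points at day 3, from 19.9, 15.2 at day 7, from 7.45, and 10.3 at day 14, from 5.38, with coarser clusters, and 15.2 and 13.9 at days 7 and 14 with more variable genes and components. With cells of at least 500 genes and at most 10% mitochondrial counts, the day 14 difference was -21.04 for macrophage-like cells, from -13.01, and 3.98 for nonclassical monocyte-like cells, from 0.0954. Of the dendritic-like cells, the cDC1-like ones, specialised in presenting antigen to CD8 T cells, were 40.6% (35.5 to 45.9) at day 0 and 16.04% (12.03 to 20.8) at day 3, and the cDC2-like ones 51.8% and 81.6% (76.6 to 85.8). At days 7 and 14 the cDC1-like share was 28.4% and 26.4%, and the cDC2-like share 50.7% and 61.9%. These shares depended on the clusters. With the clusters redrawn after 4 cells called doublets were left out, the cDC1-like difference from day 0 in percentage points was -15.2, from -24.6, at day 3, -1.998, from -12.3, at day 7 and -6.15, from -14.2, at day 14. The cDC2-like difference was then 16.9, from 29.7, at day 3, -12.2, from -1.10, at day 7 and 1.11, from 10.1, at day 14. CCR7-positive dendritic-like cells, the form that migrates to lymph nodes, were 7.56%, 2.39%, 20.9% (17.1 to 25.1) and 11.7% of the dendritic-like cells.

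Unnamed clusters held 9.47%, 3.56%, 17.6% and 8.84% of the cells outside the T class on the 4 days, and 392 of the 453 cells in the cluster led by proximal tubule genes came from day 7. A cluster made mostly of 1 library may be that library and not a cell type, and several classes were held by different clusters on different days. Of the phagocytes, 874 of 1642 at day 0 fell in cluster 4, a macrophage-like one, and 245 of 727 at day 7 in cluster 13, also macrophage-like. Those of day 3 were spread more widely, with 432, 400, 358 and 270 in clusters 10, 11, 14 and 16. A further 212, 203, 195 and 85 of them were in clusters 23, 4, 21 and 13. Of the B-like cells, 1252 of 1566 at day 0 fell in cluster 2 and 169 of 194 at day 7 in cluster 15, and of the NK-like cells of day 7, 313 of 365 fell in cluster 18. The phagocyte share depended on the clusters. With the clusters redrawn after 4 cells called doublets were left out, the day 3 difference was 11.2 percentage points, and with each cell assigned by its own markers the day 7 difference turned from -7.18 to 6.36 percentage points. The ILC2-like differences at days 7 and 14 also turned positive in that assignment, to 0.0875 and 0.709 percentage points.

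**Figure D1:**
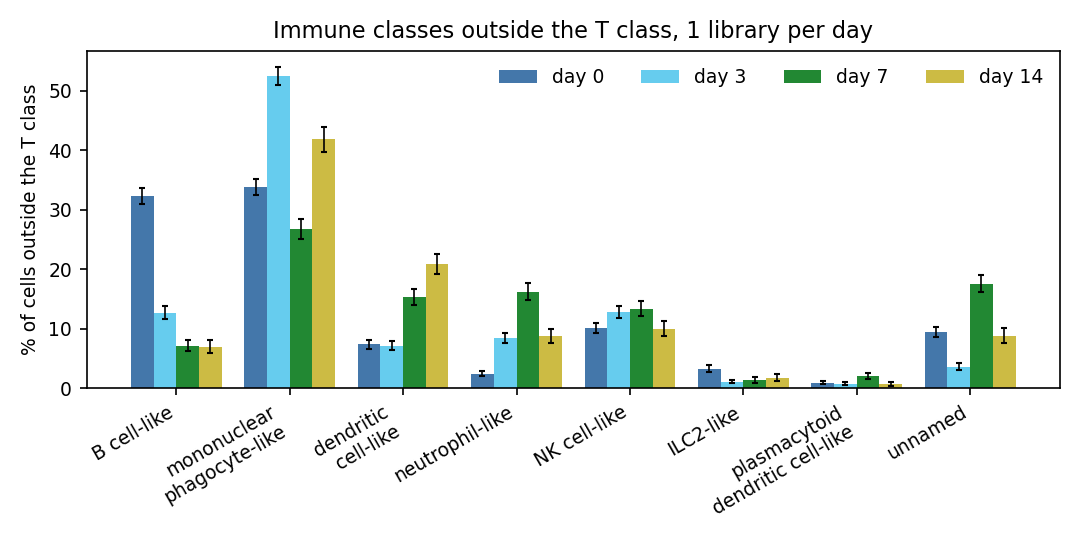
Shares of immune classes among the cells outside the T class (percent, with 95% Clopper-Pearson intervals that cover counting error only) on days 0, 3, 7 and 14, 1 library each. The B-like share was 32.3% at day 0 and 7.13% at day 7, and the neutrophil-like share 2.39% and 16.2%.

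The next comparison asked which T cell subsets were present on each day. At day 7 Th17-like cells, CD4 T cells that make interleukin 17 and recruit neutrophils, were 15.6% (14.4 to 16.97) of the T cells against 0.742% (0.447 to 1.16) at day 0. Gamma-delta-like T cells, another source of interleukin 17, were 17.6% (16.3 to 18.98) against 1.13% (0.759 to 1.62). Regulatory T-like (Treg-like) cells, which restrain immune responses, were most abundant at day 14, with 15.6% (14.05 to 17.2) against 1.05% (0.696 to 1.53) at day 0. Naive-like T cells, which recirculate through lymphoid organs, were 23.9% (22.3 to 25.6) at day 0 and 4.16% (3.49 to 4.92) at day 7. Of these, 541 of 613 at day 0 fell in T cluster 3 and 83 of 130 at day 7 in T cluster 11. T cluster 11 had a median of 1021 counts per cell and the proximal tubule and neutrophil lists among its leading ones. The share of its cells with Cd3d, Cd3e or Cd3g, taken gene by gene and averaged over these genes, was 30.9%. T cluster 3 alone held 21.1% of the T cells at day 0 and 1.504% at day 7.

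In percentage points, the day 7 library differed from day 0 by 14.9 for Th17-like cells (13.6 to 16.3), by 16.5 for gamma-delta-like cells (15.1 to 17.9) and by -19.8 for naive-like cells (-21.6 to -18.0). The Treg-like difference at day 14 was 14.5 percentage points (12.9 to 16.1). Th17-like cells were 2.36% at day 3 and 3.81% at day 14, and gamma-delta-like cells 3.45% and 9.56%. Treg-like cells held 1.77% at day 3 and 2.69% at day 7, and naive-like cells 25.4% at day 3 and 4.596% at day 14. CD8 effector or memory-like cells, which kill target cells, were 19.3%, 22.4%, 5.98% (5.18 to 6.87) and 21.4% on the 4 days.

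Single genes were also counted in T cells thinned to 1053 counts each, with B-like cells treated in the same way as the background that free RNA gives. Il17a, the gene of interleukin 17A, was seen in 1.32%, 4.20%, 22.5% and 8.05% of the thinned T cells on the 4 days, against 0%, 0%, 2.74% and 0.725% of the B-like cells. Foxp3, the master regulator of Treg cells, was seen in 0.702%, 1.44%, 1.63% and 6.68% of the T cells, against 0%, 0.464%, 0.685% and 0.725% of the B-like cells. Ifng, the gene of interferon gamma, was seen in 32.2%, 24.2%, 15.9% and 17.7%, against 0.960%, 0.696%, 3.42% and 0.725%. Trdc, the constant region of the delta chain, was seen in 1.71%, 2.99%, 9.63% and 5.63%, against 0.0800%, 0.232%, 2.05% and 0%. Cd4 was seen in 10.9%, 7.52%, 14.6% and 12.7%, against 0.0800%, 0%, 1.37% and 0.725%, and Cd8a in 17.3%, 16.2%, 12.3% and 16.1%, against 0%, 0%, 3.42% and 0%. The median depth before thinning was 3231, 3789, 2981 and 3568 counts in T cells and 2432, 2586, 1251 and 2952 in B-like cells. Left out as shallower than the thinned depth were 282, 111, 237 and 254 T cells and 316, 90, 48 and 17 B-like cells. Without thinning, the shares of T cells were 1.52%, 4.33%, 26.8% and 9.33% for Il17a, 1.29%, 3.05%, 3.04% and 13.05% for Foxp3, 46.5%, 35.6%, 26.4% and 29.3% for Ifng, 3.28%, 6.11%, 17.9% and 10.2% for Trdc, 22.9%, 18.9%, 27.8% and 29.4% for Cd4 and 28.4%, 29.95%, 19.9% and 25.8% for Cd8a.

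Unnamed T clusters held 53.8%, 44.6%, 53.9% and 45.1% of the T cells, and the thresholds that left a cluster unnamed or mixed were set after the data had been seen. 3 of these clusters, with few counts and the proximal tubule list among their leading lists, held 11.4%, 14.1%, 43.4% and 11.9% of the T cells. The largest of them had 1340 of its 1485 cells from day 7, and a receptor chain was found for 34.03% of those. Without these clusters the day 7 differences were 26.8 percentage points for Th17-like and 29.8 for gamma-delta-like cells. Among T cells with an alpha or beta receptor chain they were 29.0 and 3.68, a set that leaves out most gamma-delta cells by its construction. The total of the unnamed T clusters held opposite differences. T cluster 2, with the CD4 T and Th1 lists among its leading ones, held 21.7%, 14.4%, 1.73% and 17.6% of the T cells on the 4 days. The largest of the clusters with the tubule list held 1.01%, 6.90%, 42.9% and 2.27%.

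**Figure D2:**
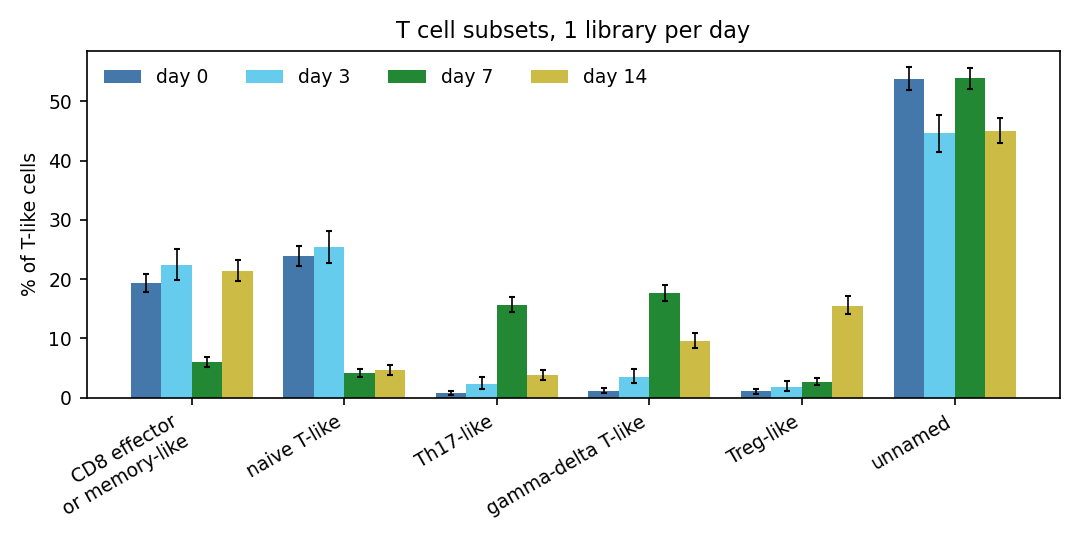
Shares of T cell subsets among T cells (percent, with 95% Clopper-Pearson intervals that cover counting error only) on days 0, 3, 7 and 14, 1 library each. Th17-like cells were 15.6% at day 7, and Treg-like cells 15.6% at day 14.

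Gene expression in T cells was compared between each disease day and day 0 to see which programmes the T cells carried. Counts were summed over the T cells of a library and scaled by that sum to CPM, the field's usual unit for a gene's share of all counts. Il17a stood at 58.6 CPM at day 0, 339.7 at day 3, 2135 at day 7 and 644 at day 14, and was 36.4-fold (33.4 to 39.9) higher at day 7 than at day 0. The type 17 list as a whole had a median log2 ratio to day 0 of 0.997 (0.704 to 1.15) at day 3, 2.84 (2.56 to 3.23) at day 7 and 1.88 (1.59 to 1.96) at day 14. Type 1 and cytotoxic genes, which serve cell killing and interferon production, were lower at day 7, with a median of -1.01 (-1.05 to -0.93). Regulatory genes stood highest at day 14, with a median of 1.99 (1.86 to 2.08), and genes of naive and recirculating T cells were lower at day 7, with -1.63 (-1.73 to -1.54), and at day 14, with -1.19 (-1.28 to -1.15).

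In the type 17 list, 11 of 11 measured members were at least 2-fold higher at day 7 with an interval that excluded 1, and 7 at day 14. Il17f, a second interleukin 17 gene, was 23.8-fold (13.8 to 45.2) higher at day 7, and Ccr6, a chemokine receptor of Th17 cells, 7.23-fold (5.49 to 9.68). The type 2 list, with genes of T helper 2 cells and of tissue repair, had medians of 0.015, 2.31 and 1.42 at days 3, 7 and 14, and its members did not move together. At day 7 5 of its 8 measured members were at least 2-fold higher and 1 at least 2-fold lower. With members at 0 counts set to their floor of 3 counts, its day 3 median was -0.16, the 1 median that differed among the 105 of the lists described here. Areg, which encodes the growth factor amphiregulin, was 22.2-fold (18.997 to 26.2) higher at day 7 and 16.5-fold (14.02 to 19.4) at day 14, and Il1rl1, the receptor of the alarmin interleukin 33, 27.1-fold (15.6 to 51.4) at day 14. Il1rl1 and Ccr8, both members of this list, were among the leading genes of the Treg-like T cluster. That cluster held 27 cells at day 0 and 335 at day 14, so the Il1rl1 difference does not by itself show a type 2 programme. Il13 was 7.02-fold (4.86 to 10.5) higher at day 7, while Il4, another type 2 cytokine gene, was 4.44-fold (3.73 to 5.30) lower at day 14 than at day 0. Of its T cell counts at day 0, 83.6% were in T cluster 9, where 84.7% of the cells with both chains carried TRAV11 with TRAJ18, the chains of invariant natural killer T (iNKT) cells, and which fell from 11.4% of the T cells at day 0 to 1.07% at day 14. Without this cluster Il4 was 1.27-fold (0.968 to 1.67) lower at day 14, so most of the difference lay in that cluster. Il5 had 0 counts at day 0, and its 3.43 CPM at day 14 were at least 9.90-fold higher than the 3 counts that a count of 0 allows. In the regulatory list 8 of 10 members were at least 2-fold higher at day 14, among them Foxp3 at 13.2-fold (10.1 to 17.6), the costimulatory receptor genes Tnfrsf9 at 9.01-fold (7.66 to 10.7) and Tnfrsf4 at 4.70-fold (4.32 to 5.11), and Il2ra, a chain of the interleukin 2 receptor, at 5.62-fold (4.64 to 6.86).

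In the type 1 and cytotoxic list 7 of 14 members were at least 2-fold lower at day 7 and 1 was 2-fold higher. Among random lists matched on expression, the median of this list at day 7 was at percentile 0, that of the type 17 list at percentile 100 and that of the regulatory list at day 14 at percentile 100. The chemokine gene Ccl5 stood at 4830 CPM at day 0 and 2143 at day 7, and Ifng at 679 and 216. The list's median was 0.13 at day 3 and -0.125 at day 14. In the naive and recirculation list 6 of 10 members were at least 2-fold lower at day 7 and 8 at day 14. Ccr7, the receptor that guides T cells to lymph nodes, was 5.15-fold (4.75 to 5.59) lower at day 7 and 4.18-fold (3.85 to 4.55) at day 14, and Klf2, a regulator of recirculation, 3.75-fold (3.66 to 3.84) at day 7. That list's day 3 median was 0.023. Activation and checkpoint genes had medians of -0.35, 0.40 and 0.34 at days 3, 7 and 14, tissue residency genes -0.37, 0.201 and 0.125, type I interferon response genes -0.118, -0.046 and 0.031 and proliferation genes 0.99, 0.33 and 0.34. Of these, the costimulator gene Icos was 2.81-fold (2.66 to 2.97) higher at day 7, and the cell cycle gene Mki67 2.09-fold (1.83 to 2.38) higher at day 3 and 3.16-fold (2.85 to 3.51) at day 7. Dissociation and stress genes, which respond within minutes to handling as well as to activation, were lower on all disease days, with medians of -0.71, -0.9998 and -0.67.

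By the rule for named genes, the highest at day 3 were Chil3, Tgfbi, Lyz2, Ccl2 and Alox5ap, which are genes of monocytes and macrophages. Chil3 was 65.8-fold (25.1 to 245) higher than at day 0 at 30.4 CPM, below the 49.8 in B-like cells, and at 0.124 counts per cell in T cells and 0.127 in B-like cells. At day 7 they were Il17a, Spp1, Ngp, Bcl2a1a and Lcn2, and Spp1, which encodes the matrix protein osteopontin, stood at 187 CPM in T cells against 630.3 in B-like cells of the same library. Its mean counts per cell were 0.640 and 0.983. Ngp and Lcn2 are neutrophil genes, and the neutrophil genes S100a8 and S100a9 together stood at 294 CPM in T cells of day 7 against 766 in B-like cells. Per cell the mean counts were 0.490 and 0.559 for S100a8 and 0.517 and 0.640 for S100a9. Proximal tubule genes stood at 22.6, 72.7, 251 and 167 CPM in T cells on the 4 days, and at 1109 in B-like cells of day 7. The B-like cells of day 7 were shallower, with a median of 1251 counts against 2981 in T cells. This raises their CPM where counts per cell are equal. Lists of phagocyte genes were higher in the T cells of that day too, with medians of 2.49 for matrix and repair and 2.13 for immature myeloid and alarmin genes. At day 14 the highest were Il1rl1, Areg, Igfbp7 at 18.2-fold (12.8 to 26.7), Neb at 17.2-fold (10.7 to 29.4) and Foxp3. Only 1 of these 5, Areg, was kept with the 7 T clusters of at least 20 cells in every library summed by counts. With no filter on low counts 3 were kept, and with the other settings 4 or 5. Of these genes, Foxp3, Neb and Il1rl1 were among the leading genes of the Treg-like T cluster. Igfbp7 and Areg were among those of the unnamed T cluster 16, which held 9 cells at day 0 and 71 at day 14. The lowest at day 3 were AY036118, Zfp683, Ciart, Egr1 and Dnaja4. Of these, Zfp683, a regulator of tissue-resident T cells, was 4.57-fold (3.55 to 5.97) lower, and the immediate early gene Egr1 3.42-fold (3.18 to 3.69). At day 7 they were AY036118, Jchain, Igfbp4, Ly6c1 and Dapl1, and at day 14 Igfbp4, Ccr7, Ly6c1, Il4 and Tubb2a. Igfbp4, a gene of naive T cells, was 8.72-fold (7.24 to 10.6) lower at day 7. AY036118, a non-coding RNA gene, was 19.3-fold (16.8 to 22.3) lower at day 3, but it was lower in all 6 classes at days 3 and 7, with 929, 48.2, 66.8 and 966 CPM in T cells on the 4 days, 865, 6.01, 17.02 and 613 in NK-like cells, 441, 4.52, 59.4 and 567 in B-like cells and 1057, 422, 75.6 and 1306 in phagocytes. That is a pattern of the libraries and not of 1 cell class.

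On the genome build GRCm38, Il17a lies on chromosome 1, 20730905 to 20734496, Areg on chromosome 5, 91139599 to 91148432, Il1rl1 on chromosome 1, 40429570 to 40465415 and Foxp3 on chromosome X, 7573644 to 7595245. The median log2 ratio over all measured genes of the T cells was -0.103 at day 3, 0.11 at day 7 and 0.038 at day 14, so that list medians relative to it were 2.73 for type 17 at day 7, -1.12 for type 1 at day 7 and 1.95 for the regulatory list at day 14. With the 7 T clusters that had at least 20 cells in every library weighing the same, the type 17 median was 0.36 at day 7 and 0.14 at day 14, the regulatory median 0.17 at day 14, the type 1 median -0.51 at day 7, the naive median -0.39 at day 7 and the type 2 median 0.68 at day 14. That weighting turned the activation and checkpoint medians to -0.14 at day 7 and -0.087 at day 14, and the regulatory medians to -0.14 at day 3 and -0.054 at day 7, from 0.11 and 0.84. It left out 10 of the 17 T clusters, among them the Th17-like one, with 19 cells at day 0, and the Treg-like one, with 18 at day 3. Leaving them out was therefore also tried without equal weights. Summed by their counts, the 7 clusters had a type 17 median of 3.90 at day 7 and 2.17 at day 14, a regulatory median of 0.248 at day 7 and 0.22 at day 14, and a type 1 median of -0.59 at day 7 and 0.1903 at day 14. With all 17 clusters weighing the same, some of them with as few as 2 cells in a library, the type 17 median was 0.34 at day 7 and 0.255 at day 14, the regulatory median 0.122 at day 14, the type 1 median -0.41 at day 7, the naive median -0.39 at day 7 and -0.028 at day 14 and the type 2 median 0.87 at day 14. The type 2 median of day 7 was 1.65 with the 7 clusters equal, 3.45 with the 7 by counts, 1.18 with all 17 equal and 1.23 without the tubule-RNA clusters. The type 17 median of day 3 was 0.0089 with the 7 equal and 0.11 with all 17 equal, from 0.997. With the 7 equal the proliferation median of day 3 was 0.15 and the naive median of day 14 -0.42. Medians that turned with all 17 clusters included activation and checkpoint, to -0.14 at day 7 and -0.16 at day 14, tissue residency, to -0.14 and -0.100, proliferation, to -0.043 at day 3 and -0.18 at day 14, and regulatory, to -0.081 at day 3. Single genes also moved with the weights. The log2 ratio of Il17a at day 7, 5.19, was 1.93 with the 7 clusters equal, 6.15 with the 7 clusters by counts and 1.26 with all 17 equal. In the same order Foxp3 at day 14, 3.73, was 1.21, 0.82 and 0.76, and Areg at day 14, 4.04, was 2.13, 3.13 and 2.29. With all 17 equal, Il1rl1 at day 14 was 2.23, from 4.76, Neb at day 14 0.904, from 4.10, Igfbp4 at day 7 -0.64, from -3.12, and Ccr7 at day 14 -0.0088, from -2.06. The log2 ratios of Dapl1 at day 7 and of Il4 and Igfbp4 at day 14 turned to 0.092, 0.055 and 0.116. The clusters were drawn from the expression of the same cells.

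Mononuclear phagocytes were compared in the same way, to see how their state differed along the disease. At day 3 they had lower levels of the genes that present antigen to CD4 T cells, with a median log2 ratio to day 0 of -2.35 (-2.37 to -2.26) for the class II list, which was -0.803 (-0.83 to -0.77) at day 7 and -0.26 (-0.41 to -0.247) at day 14. The immature myeloid and alarmin list, which holds genes of freshly recruited monocytes and the alarmin genes S100a8 and S100a9 of neutrophils, was higher, with 2.05 (1.95 to 2.15) at day 3, 1.94 (1.86 to 2.02) at day 7 and 1.06 (1.002 to 1.12) at day 14. Proliferation genes were higher at day 3, with 2.18 (1.96 to 2.30), and type I interferon response genes, an antiviral programme, were lower, with -1.36 (-1.49 to -1.23). Matrix and repair genes were higher at day 7, with 1.49 (1.41 to 1.69), and at day 14, with 1.10 (0.877 to 1.22), after 0.38 at day 3.

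At day 3 the medians of the class II list, the immature myeloid list and the interferon list were at percentiles 0, 100 and 0 of matched random lists. In the class II list 6 of 7 members were at least 2-fold lower at day 3. Cd74, the invariant chain, stood at 48217 CPM at day 0, 9014 at day 3, 22500 at day 7 and 34390 at day 14, and H2-Aa, a class II chain, at 11435, 2239, 6599 and 9545. In the immature myeloid and alarmin list 7 of 8 members were at least 2-fold higher at day 3, among them the alarmin gene S100a8 at 13.02-fold (11.4 to 14.9), Chil3 at 7.04-fold (6.61 to 7.52), and Ccr2, the receptor that draws monocytes into tissue, at 2.73-fold (2.57 to 2.90). S100a8 stood at 537 CPM in phagocytes and 76.9 in B-like cells at day 3, where it was 8.83-fold (5.86 to 13.7) higher than at day 0, against 48730 in neutrophil-like cells. At day 7 the levels in phagocytes and B-like cells were 314 and 356 CPM for S100a8 and 267 and 409 for S100a9, while the mean counts per cell were 0.988 and 0.557 for S100a8 and 0.839 and 0.639 for S100a9. Phagocytes were thus no higher by CPM and higher per cell, and how much of these counts was free RNA stays open. Without these genes the list medians were 1.36, 1.497 and 0.698 at days 3, 7 and 14. Of the proliferation genes 10 of 12 were at least 2-fold higher at day 3, with Mki67 at 4.64-fold (3.80 to 5.70) and Stmn1 at 5.09-fold (4.36 to 5.98), and the list's medians were 0.862 at day 7 and 0.52 at day 14. Of the interferon response genes 9 of 13 were at least 2-fold lower at day 3, with Rsad2 6.47-fold (5.37 to 7.83) and Isg15 2.58-fold (2.36 to 2.82) lower, and the medians were 0.031 at day 7 and -0.1901 at day 14.

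In the matrix and repair list 10 of 17 members were at least 2-fold higher at day 7 and 9 at day 14. Spp1 stood at 24.5 CPM at day 0, 302 at day 3, 1016 at day 7 and 450.2 at day 14, and was 41.5-fold (35.0 to 49.6) higher at day 7. The fibronectin gene Fn1 was 5.98-fold (5.59 to 6.40) higher at day 7, the thrombospondin gene Thbs1 7.62-fold (7.05 to 8.24), and Gpnmb, a gene of lipid-laden and repair macrophages, 18.3-fold (10.2 to 35.6). Arg1, which encodes the arginine-degrading enzyme arginase 1, had 0 counts at day 0, and its 165 CPM at day 7 were at least 314-fold higher than the 3 counts that a count of 0 allows. Igf1, a growth factor gene, was instead 8.62-fold (6.30 to 11.99) lower at day 3. In B-like cells of day 7 Spp1 stood at 630.3 CPM, and at day 14 at 68.998. Its mean counts per cell at day 7 were 3.20 in phagocytes and 0.983 in B-like cells. Lists of T cell genes were also higher in the phagocytes of day 7, with a median of 2.32 for the type 1 and cytotoxic list.

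Among the other phagocyte lists, the inflammatory cytokine list had medians of -0.16, 1.29 and -0.18 at days 3, 7 and 14. Its members parted, with Tnf 5.36-fold (5.002 to 5.76) lower at day 3, the chemokine gene Ccl4 2.51-fold (2.44 to 2.58) lower at day 7, and the neutrophil attractant Cxcl2 2.13-fold (2.07 to 2.18) and Il1rn, which encodes the interleukin 1 receptor antagonist, 5.16-fold (4.41 to 6.05) higher at day 7. Chemokine ligands had medians of 0.37, 0.54 and 0.45, with Ccl8 10.7-fold (8.65 to 13.3) higher at day 14 and Cxcl9, an interferon gamma target, 8.75-fold (7.64 to 10.04) lower at day 3. Glycolysis and hypoxia genes had medians of 0.89, 0.83 and 0.54, and lipid handling genes -0.1998, 0.76 and 0.32, with the lipid carrier Apoe at 4485, 1861, 7790 and 7563 CPM on the 4 days. Complement genes had medians of -0.41, 0.5004 and -0.195, resident macrophage genes -0.79, 0.64 and 0.061 and Fc receptor genes, through which phagocytes bind antibody, -0.21, -0.24 and 0.11. C1qa, a chain of the first complement component, stood at 3384 CPM at day 0 and 1827 at day 3, and the macrophage gene Adgre1 at 437 and 151. Dissociation and stress genes had medians of -1.60, -1.12 and -1.02, and Dnajb1, a heat shock gene, was 12.5-fold (11.97 to 13.1) lower at day 3.

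The named genes highest at day 3 were the acute phase and alarmin genes Saa3, Lrg1 and Lcn2 with Igfbp6 and Ifitm1. Saa3 had 1 count at day 0 and 2380 at day 3, a ratio of 1116 with an interval of 200.1 to 44093. The highest at day 7 were Arg1, Timp1, Flrt3, Lrg1 and Spp1, and those at day 14 Retnla, Spp1, Lyz1, AA467197 and Ccl8. Retnla, a marker of alternatively activated macrophages, had 0 counts at day 0, and its 508 CPM at day 14 were at least 969-fold higher than the 3 counts that 0 allows. Timp1, an inhibitor of matrix-degrading enzymes, stood at 68.2 CPM at day 7, at least 130.1-fold higher by the same floor. The lowest were Mmp13, Clec9a, Dnajb1, Hsph1 and Dnase1l3 at day 3, AY036118, which was lower in every class of that library, Hspb1, Dnajb1, Srpk3 and Ccn1 at day 7, and Hs3st1, Mmp13, Hspb1, Hsph1 and Dnajb1 at day 14. Mmp13, a collagenase gene, was 23.5-fold (20.7 to 26.7) lower at day 3 and 7.72-fold (6.84 to 8.74) at day 14. Retnla lies on chromosome 16, 48842551 to 48844461, Spp1 on chromosome 5, 104435118 to 104441050 and Mmp13 on chromosome 9, 7272514 to 7283331 of the build GRCm38.

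The median over all phagocyte genes was 0.034, 0.2505 and -0.019 on days 3, 7 and 14, so that the matrix and repair median at day 7 was 1.24 relative to it, and a T cell marker count was present in 3.47%, 4.41%, 37.0% and 11.7% of the phagocytes on the 4 days. Single genes moved as well, and with equal subtypes the log2 ratio at day 3 of Mmp13 was -3.15, from -4.55, that of Dnajb1 was -2.62, from -3.65, that of Lcn2 was 4.95, from 6.63, and that of Lrg1 was 6.72, from 8.96. With every phagocyte subtype weighing the same, the immature myeloid median was 0.67 at day 3, 0.92 at day 7 and 0.065 at day 14. The inflammatory cytokine median of day 7 was then 0.52 and the interferon median of day 14 -1.06, from 1.29 and -0.1901. At day 3 the interferon response median was then -2.18 and the class II median -1.62. The complement medians of days 3 and 14 turned to 0.11 and 0.123, the resident macrophage median of day 3 to 0.123, the matrix and repair median of day 3 to -0.32, the interferon median of day 7 to -0.856, the Fc receptor median of day 7 to 0.084 and the chemokine median of day 14 to -0.13. As a mean over cells, the proliferation median was 2.94 at day 3 and 1.53 at day 7, and the complement medians of days 3 and 14, the lipid handling median of day 3 and the interferon median of day 14 turned to 0.073, 0.027, 0.030 and 0.091.

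**Figure D3:**
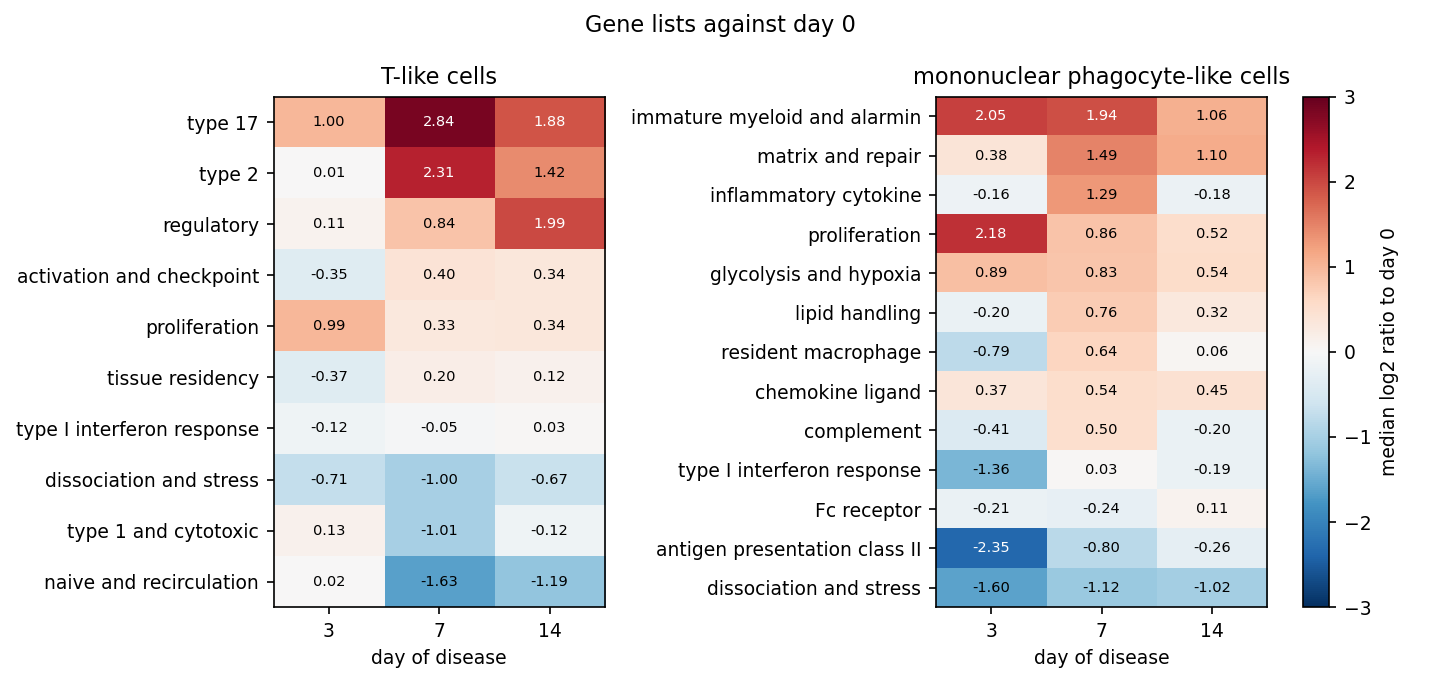
Median log2 ratio to day 0 of each gene list in T cells and mononuclear phagocytes on days 3, 7 and 14, with 1 library per day. In T cells the type 17 list had 2.84 at day 7 and the naive and recirculation list -1.63, and in phagocytes the class II list had -2.35 at day 3.

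The remaining classes with enough cells were compared by their lists and their 3 highest and 3 lowest genes. Class II genes in dendritic-like cells had medians of 0.047, -0.023 and 0.11 on days 3, 7 and 14, and the day 3 value was -0.039 with TMM scaling. Fabp5, a fatty acid carrier, was 24.2-fold (20.2 to 29.1) higher in them at day 7 and 7.49-fold (6.24 to 9.05) at day 14, and Ifitm1, an interferon-inducible membrane gene, 32.9-fold (26.9 to 40.7) at day 3. Timp1 had 0 counts at day 0 and was at least 33.3-fold, at least 40.1-fold and at least 41.0-fold higher than the 3-count floor on the 3 disease days. Cxcl9 was 12.6-fold (9.47 to 17.1) lower at day 3 and 5.06-fold (4.33 to 5.93) at day 14. Neutrophil-like cells of day 3 carried the stefin genes Stfa1, at 30.1-fold (12.9 to 93.1), and Stfa2 and Stfa3, which had 0 counts at day 0 and were at least 24.2-fold and at least 12.4-fold higher than the floor. At day 7 the neutrophil attractant Cxcl3 was 11.7-fold (8.43 to 16.8) higher in them, and the granule genes Ngp and Camp were 24.9-fold (18.9 to 33.2) and 22.6-fold (15.7 to 33.3) lower. Their 50.05 and 29.1 CPM at day 7 were no higher than the 56.1 and 42.9 in B-like cells, and the mean counts per cell were 0.141 and 0.0816, against 0.0876 and 0.0670 in B-like and 0.109 and 0.0848 in T cells. Camp was thus at background by both measures and Ngp close to it, and the folds give the least difference and not its size. Spp1 was 16.5-fold (10.5 to 27.6) higher and Retnlg, a gene of neutrophils in blood, 5.21-fold (4.77 to 5.70) lower at day 14.

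Inflammatory cytokine genes had medians of 0.089, 0.87 and 0.17 in dendritic-like cells and -0.27, 0.7399 and 0.46 in neutrophil-like cells on days 3, 7 and 14. Class II genes in neutrophil-like cells, which also measure RNA from other cells, had medians of -2.67, -0.98 and 0.65. As a mean over cells these medians were -2.21, -0.013 and 1.14. Interferon response genes in dendritic-like cells had medians of -0.61, -0.22 and -0.30, and their proliferation genes -0.23, -0.13 and -0.79. In NK-like cells proliferation genes had medians of 0.744, 0.99 and 0.94998 and type 1 and cytotoxic genes 0.066, -0.252 and -0.44. Stress genes were lower in all of these classes, with medians of -0.72, -0.81 and -0.62 in B-like, -0.66, -0.863 and -0.7396 in NK-like, -0.884, -0.85 and -0.73 in dendritic-like and -1.11, -0.42 and -0.23 in neutrophil-like cells. In B-like cells Jchain, a gene of antibody-secreting cells, had 255 counts at day 0 and 0 at day 14, at least 11.1-fold lower by the 3-count floor. Their other named genes were mostly those of other cells, such as Spp1 and Gzma at day 7 and Umod, a gene of the loop of Henle, and Cd3g at day 14. In NK-like cells Ifitm3 was 10.6-fold (6.02 to 20.2) higher at day 3 and 31.9-fold (18.2 to 61.0) at day 7, but its 81.3 and 246 CPM were below the 130.4 and 389 in B-like cells of the same libraries and its mean counts per cell, 0.336 and 0.553, compared with 0.332 and 0.608 there, so these counts are read as background. Genes of macrophages in NK-like cells stood at 79.9, 196 and 724 CPM on days 0, 3 and 7, and those of the proximal tubule at 15.4, 65.2 and 539.6. Zfp683 was 6.78-fold (4.36 to 10.97) lower in NK-like cells at day 3. The T cluster counted with the NK-like cells made up 237 of 488 at day 0 and 68 of 524 at day 3. Comparisons of NK-like cells thus set different mixtures of clusters against each other. The all-gene medians of these classes were between -0.18, in NK-like cells at day 3, and 0.30, in B-like cells at day 7, with 0.251 in dendritic-like cells at day 7 and 0.16 in neutrophil-like cells at day 14. The neutrophil class held 116 cells at day 0, and the B class 194 cells at day 7, which limits their values.

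The T cell receptor sequences were compared to see how large single clonotypes were in the kidney on each day. The day 7 repertoire was dominated by 1 clonotype, that is a set of cells with the same alpha and beta chains. It held 189 of 1244 cells, or 15.2% (13.2 to 17.3), and 140 of its 153 cells in the expression table were Th17-like. Its chains were TRAV12-1 TRAJ30 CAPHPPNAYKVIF with TRBV13-1 TRBJ2-7 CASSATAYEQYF. Invariant natural killer T (iNKT) chains, TRAV11 with TRAJ18, which recognise lipids, were carried by 14.04% of the cells at day 0 (12.5 to 15.7), 7.53% at day 3, 1.61% at day 7 and 2.35% at day 14. Cells in clonotypes of at least 2 cells were 34.8%, 23.4%, 42.9% and 37.1% of the cells on days 0, 3, 7 and 14. This share rises with the number of cells sampled, which differed between the libraries, and it was not thinned. The days cannot be ranked by it. At an equal 770 cells, days 3 and 14 had 634 and 639 distinct clonotypes.

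Cells with exactly 1 beta chain and 1 or 2 alpha chains numbered 1937, 770, 1244 and 1747, in 1376, 634, 799 and 1302 clonotypes. The 10 largest clonotypes held 15.9%, 13.8%, 26.3% and 8.64% of the cells. Shannon evenness, which is 1 when all clonotypes are of equal size, was 0.927, 0.959, 0.874 and 0.968. With every library thinned to the 770 cells of day 3, the mean number of distinct clonotypes was 589, 634, 519.9 and 639, with 95% ranges over draws of 570 to 608 at day 0, 504 to 536 at day 7 and 623 to 655 at day 14. The largest day 0 clonotypes were TRAV7-4 TRAJ30 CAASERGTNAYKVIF with TRBV10 TRBJ1-2 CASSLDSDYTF, with 104 cells, and TRAV7-4 TRAJ39 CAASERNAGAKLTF with TRBV10 TRBJ2-5 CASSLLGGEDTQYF, with 63 cells. Most of their cells fell in unnamed T clusters, 70 of 73 for the larger. At day 3 the largest was TRAV13D-2 TRAJ37 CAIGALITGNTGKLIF with TRBV12-2 TRBJ1-6 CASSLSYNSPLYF, with 46 cells, and at day 14 TRAV12-2 TRAJ22 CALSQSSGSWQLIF with TRBV3 TRBJ1-4 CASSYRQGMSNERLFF, with 24 cells, both mostly CD8 effector or memory-like. Ranks 2 to 5 held 63 to 21 cells at day 0, 10 to 8 at day 3, 33 to 14 at day 7 and 19 to 14 at day 14. Chains of mucosal-associated invariant T cells, TRAV1 with TRAJ33, were found in 5, 5, 7 and 3 cells.

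Of the CD8 effector or memory-like cells with a receptor, 69.1%, 55.3%, 54.0% and 60.8% belonged to clonotypes of at least 2 cells on the 4 days. Among Th17-like cells the share was 70.5% of 322 cells at day 7 and 39.0% of 59 at day 14. Of the 227 Th17-like cells in such clonotypes at day 7, 140 belonged to the largest one, and without it the share was 47.8% (40.4 to 55.3) of 182 cells. Among Treg-like cells it was 5.13% of 39 cells at day 7 and 36.8% of 204 at day 14. In naive-like cells it was 0.938% at day 0 and 17.3% at day 14. These shares within subsets were not thinned either and rise with the number of cells sampled, so they cannot be compared directly between days. The beta chain genes with the widest range of use were TRBV13-1, at 5.63%, 7.66%, 21.5% and 4.01%, TRBV10, at 11.6%, 2.34%, 3.14% and 3.32%, and TRBV12-2, at 3.36%, 10.8%, 2.73% and 3.38%. In each case the largest clonotype of 1 day carried the gene. Hardly any clonotype was found on more than 1 day, with 1 shared between days 0 and 14, 2 between days 7 and 14 and 0 in each of the other 4 pairs, and with 1 library per day a clone of 1 animal cannot be told from a clone of the disease stage. A receptor chain was found for 75.1%, 71.3%, 44.5% and 70.6% of the T-like cells on the 4 days.

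**Figure D4:**
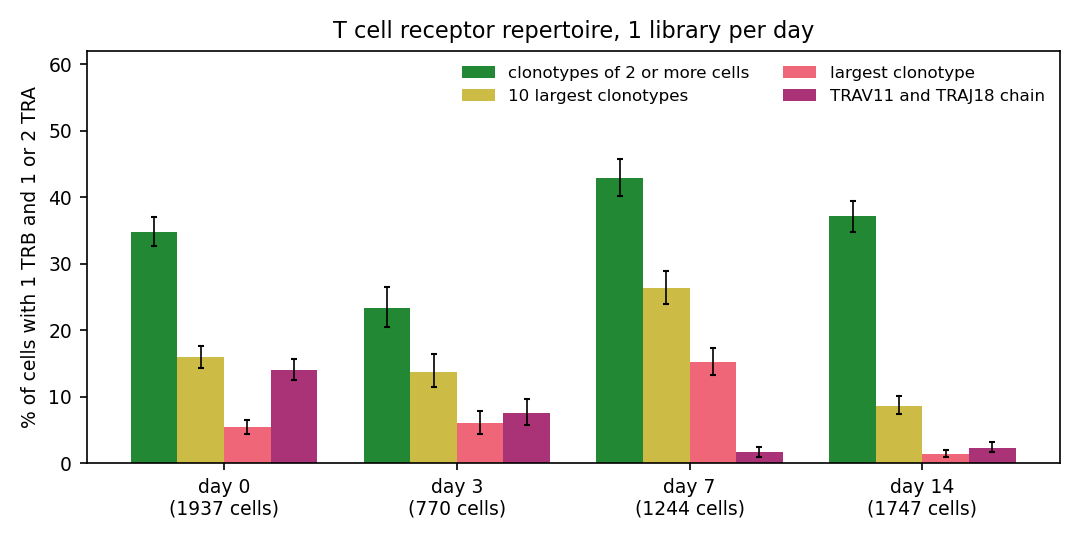
T cell receptor measures on days 0, 3, 7 and 14, 1 library each, as percent of cells with 1 beta chain and 1 or 2 alpha chains, with 95% Clopper-Pearson intervals that cover counting error only. The largest clonotype held 15.2% at day 7 and the iNKT chains 14.04% at day 0. The share in clonotypes of 2 or more cells rises with the number of cells sampled and was not thinned.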

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

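The tests in this part were chosen after the results were seen, except the one for barcode reading errors. All were run on the same 4 libraries in which the patterns were found. Cells of an unnamed cluster led by proximal tubule genes, a signal outside the immune classes compared, made up 0.508% of the cells at day 3, 6.70% at day 7 and 0.778% at day 14, against 0.0135% at day 0. T cell receptor chains were found in 2.59% of the mononuclear phagocytes at day 14 (24 of 928), above the 0.609% at day 0.

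T cells of day 7 carried genes of phagocytes, neutrophils and kidney tubules, such as Spp1, S100a8 and Kap. Expression by the T cells themselves would need levels well above those of B-like cells, but only 9.30% of the 43 genes stood at 4 or more times the B-like level. Droplets with a second cell would hold more RNA. The 782 T cells with the most of these genes had a median count of the other genes 0.881 times that of the rest. This split was used because 99.8% of the T cells had some count of them. It was not made within T clusters. T cluster 0, with 1340 cells of day 7 and a median of 1519 counts, had Spp1, S100a8 and Kap among its leading genes. Its low depth can lower the ratio, so this value cannot decide whether second cells were present. Free RNA in every droplet of that library remained a candidate explanation, since B-like cells held about as much as T cells, with a median log2 ratio of 0.45, and 38 genes lay within 4-fold. No biological explanation other than expression by the T cells was tested.

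The largest day 7 clonotype held 189 cells. Receptor RNA of 1 cell spread over droplets would fall on T cells of any kind, but 91.5% of its cells were Th17-like against 22.8% of the other day 7 cells with a receptor, a difference of 68.7 percentage points. Of its barcodes 0% differed from another at 1 position, the closest pair being 3 positions apart. Barcodes that differ by a reading error may already have been merged in the Cell Ranger processing. This value therefore cannot decide whether 1 cell was counted under several such barcodes. The clonotype had 0 cells in the other 3 libraries, but growth of a T cell clone at day 7 of the disease and a clone private to the animals of that library cannot be told apart, because there was 1 library of day 7.

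Dissociation and stress genes were lower than at day 0 in every class and on every disease day compared, with the highest of the 18 list medians at -0.23 and the lowest at -1.60. Of these medians 17 were below percentile 2.5 of matched random lists, and the highest percentile was 18.4. A shift of all genes from the scaling by class totals was too small, since the lowest of the all-gene medians was -0.18. A difference between the libraries in handling before lysis may account for the pattern, as such genes respond in all cell types at once. The disease stays open, and with 1 library per day it cannot be told apart from handling.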

How the results depend on the processing

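Across 271 results and 1565 alternative values, 1109 stayed within the counting interval, 427 moved beyond it and 29 turned, that is changed sign where the interval of the main value left out 0. Counting main values whose interval held 0 as well, 59 alternative values had the other sign. The 27 main values of the comparisons, picked after the data were examined, had 189 alternatives, of which 128 stayed within the interval and 61 moved, and 149 of 149 signed ones kept their sign. Of the 366 other moved values, 221 moved toward 0 and 145 away from it. Of the 55 single-gene ratios, 46 moved by more than 1.5-fold under at least 1 alternative, 27 of them where T clusters were left out or weighed the same. Of the 105 list medians, 24 moved by more than that, 11 of them in T cells and 12 in phagocytes. The alternatives without unnamed cells, without high doublet scores, without tubule-RNA T clusters (for shares and for expression), without invariant receptors, with equal phagocyte subtypes, without S100a8 and S100a9 in the immature myeloid list, without the T cluster of iNKT receptors for Il4, with the 7 T clusters summed by counts, with all 17 T clusters equal, with values raised to whole numbers, with no count filter for phagocytes, and with means over cells for the other classes, were chosen after the data were seen, and the rest before. No paired analysis was possible because each day had 1 library. Counting intervals leave the spread between animals unknown.

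Differences of shares are in percentage points from day 0, receptor shares in percent and list and gene values in log2 ratios to day 0, each with its main value in brackets. Among T cells with a receptor chain, the values were Th17 day 7 29.0 (from 14.9), gamma-delta T day 7 3.68 (from 16.5) and naive T day 7 -21.6 (from -19.8). Without the unnamed T clusters with tubule RNA, the values were Th17 day 7 26.8 (from 14.9), Treg day 14 16.5 (from 14.5), gamma-delta T day 7 29.8 (from 16.5), type 1 day 7 -1.20 (from -1.01) and naive list day 7 -1.83 (from -1.63). With more variable genes and components, the values were naive T day 7 -21.8 (from -19.8), dendritic cell day 14 15.6 (from 13.5) and phagocyte day 3 13.8 (from 18.6). With each cell assigned by its markers, the values were B cell day 7 -26.9 (from -25.2), ILC2 day 7 0.0875 (from -1.94), ILC2 day 14 0.709 (from -1.54), dendritic cell day 14 10.5 (from 13.5), phagocyte day 7 6.36 (from -7.18) and neutrophil day 7 15.5 (from 13.8). Without unnamed cells, the values were B cell day 7 -27.1 (from -25.2) and neutrophil day 7 17.02 (from 13.8). Without the 5% of cells with the highest doublet score, the value was B cell day 7 -27.2 (from -25.2). Without the cells called doublets, the value was phagocyte day 3 11.2 (from 18.6). With cells of at least 500 genes and at most 10% mitochondrial counts, the value was phagocyte day 3 14.7 (from 18.6). Without invariant receptors, the value was clonotypes of 2 or more cells day 0 40 (from 34.8). By the beta chain alone, the values were iNKT chain day 0 11.2 (from 14.04), clonotypes of 2 or more cells day 7 50.2 (from 42.9) and clonotypes of 2 or more cells day 14 42.1 (from 37.1). With barcodes in the expression table only, the value was clonotypes of 2 or more cells day 14 33.9 (from 37.1). As a mean over cells, the values were type 17 day 7 2.54 (from 2.84), type 1 day 7 -0.8599 (from -1.01), naive list day 7 -1.05 (from -1.63), interferon day 14 0.091 (from -0.1901), class II day 3 -2.39 (from -2.35), matrix and repair day 7 1.28 (from 1.49), matrix and repair day 14 0.81 (from 1.10), complement day 3 0.073 (from -0.41), complement day 14 0.027 (from -0.195), proliferation day 3 2.94 (from 2.18) and lipid handling day 3 0.030 (from -0.1998). With the 7 T clusters of at least 20 cells in every library weighing the same, the values were type 17 day 7 0.36 (from 2.84), type 17 day 14 0.14 (from 1.88), type 1 day 7 -0.51 (from -1.01), type 2 day 14 0.68 (from 1.42), regulatory day 3 -0.14 (from 0.11), regulatory day 7 -0.054 (from 0.84), regulatory day 14 0.17 (from 1.99), activation day 7 -0.14 (from 0.40), activation day 14 -0.087 (from 0.34), naive list day 7 -0.39 (from -1.63), proliferation day 14 -0.00082 (from 0.34) and Ly6c1 day 14 0.0016 (from -2.30). With those 7 T clusters summed by counts, the values were type 17 day 7 3.90 (from 2.84), type 17 day 14 2.17 (from 1.88), type 1 day 7 -0.59 (from -1.01), type 1 day 14 0.1903 (from -0.125), type 2 day 14 0.85 (from 1.42), regulatory day 14 0.22 (from 1.99) and naive list day 7 -1.76 (from -1.63). With all 17 T clusters weighing the same, the values were type 17 day 7 0.34 (from 2.84), type 17 day 14 0.255 (from 1.88), type 1 day 7 -0.41 (from -1.01), type 2 day 14 0.87 (from 1.42), regulatory day 3 -0.081 (from 0.11), regulatory day 14 0.122 (from 1.99), activation day 7 -0.14 (from 0.40), activation day 14 -0.16 (from 0.34), tissue residency day 7 -0.14 (from 0.201), tissue residency day 14 -0.100 (from 0.125), naive list day 7 -0.39 (from -1.63), proliferation day 3 -0.043 (from 0.99), proliferation day 14 -0.18 (from 0.34), Dapl1 day 7 0.092 (from -2.85), Il4 day 14 0.055 (from -2.15) and Igfbp4 day 14 0.116 (from -2.48). With TMM scaling, the values were type 1 day 7 -1.11 (from -1.01), naive list day 7 -1.74 (from -1.63), class II day 3 -2.40 (from -2.35) and matrix and repair day 7 1.18 (from 1.49). With every phagocyte subtype weighing the same, the values were interferon day 3 -2.18 (from -1.36), class II day 3 -1.62 (from -2.35), chemokine ligand day 14 -0.13 (from 0.45), matrix and repair day 14 0.858 (from 1.10), complement day 3 0.11 (from -0.41), complement day 14 0.123 (from -0.195), Fc receptor day 7 0.084 (from -0.24), proliferation day 3 2.79 (from 2.18), immature myeloid day 3 0.67 (from 2.05) and resident macrophage day 3 0.123 (from -0.79). Without phagocytes holding a T cell marker count, the values were class II day 3 -2.40 (from -2.35) and proliferation day 3 2.33 (from 2.18). Without S100a8 and S100a9 in its list, the value was immature myeloid day 3 1.36 (from 2.05). The chain requirement removes gamma-delta cells by construction. The 7 T clusters leave out the Th17-like and Treg-like clusters by construction. Leaving clusters out, with no change of weights, took the regulatory median of day 14 to 0.22 and the type 17 median of day 7 to 3.90, and equal weights with no cluster left out took them to 0.122 and 0.34. The regulatory median thus fell under either change alone, so its fall cannot be put down to one of them, while the type 17 median fell with equal weights only. For the other settings the cause was not tested.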

Other observations

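Both hypotheses in this part were tested after the pattern had been seen. T cluster 9 was left unnamed, and the NKT list was not among those that could name a T cluster. It expressed Il4, a type 2 cytokine gene, together with Ifng, a type 1 cytokine gene. It also expressed Zbtb16, the transcription factor gene of innate-like T cells. Il4 was seen in 50% of its cells against 1.32% of the other T cells, Ifng in 72.7% against 32.3%, Zbtb16 in 24.9% against 6.61% and Zfp683 in 45.2% against 7.86%. A candidate explanation is that these were iNKT cells. Of its cells with both chains, 183 of 216, or 84.7% (79.2 to 89.2), carried TRAV11 with TRAJ18, against 3.14% in the other T clusters.

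The largest 2 clonotypes of day 0 shared the genes TRAV7-4 and TRBV10 and held 167 cells, or 8.62% of the day 0 cells. A receptor family shared by many clonotypes was tested as the source. Of the day 0 clonotypes 2 paired these genes, which argues against such a family, and 1 cell did so at day 14 and 0 at days 3 and 7. As a check of the animals, the Y-linked gene Ddx3y stood at 58.6, 47.7, 63.8 and 56.9 CPM over all cells of the 4 libraries and Eif2s3y at 60.4, 50.1, 51.5 and 50.9, while Xist, expressed from the inactive X chromosome, stood at 0, 0, 0.0391 and 0.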
